A study of Homo sapiens with 6 samples.

How the data were processed

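Chromatin accessibility was measured by ATAC-seq in A375 human melanoma cells. The libraries formed 3 groups of 2, taken from the labels: untreated cells (mock), cells given recombinant HMGA1 for 2 h and cells given it for 18 h. The labels' protocols call the 2 libraries of a group biological replicates and do not say whether they came from separate cultures, so the p-values measure the spread between these libraries, part of which may be technical. Per the labels' protocols, cells were frozen after treatment and a service provider made the libraries with the Tn5 transposase and sequenced them as read pairs.

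Per the submitters' processing notes, the genome build was hg38, reads were demultiplexed with bcl2fastq 2.17, and the authors used DESeq2, for which no version is named there. The aligner, the peak caller, the read counter and any shift of read ends for the Tn5 insertion were not given in the sources used here. The files used here are the 3 tables of the authors' own pairwise comparisons, and 0 of their columns hold the values of 1 library. Each row gave a region, a gene name with the distance to its start, the mean signal of the region over the 6 libraries as deposited (read counts divided by the authors' size factors), the log2 fold change and its standard error, the Wald statistic as a score (the log2 fold change divided by its standard error, by the authors), and the deposited two-sided p-value with its adjusted p. The mean signal was identical between the deposited tables for every shared region, and the deposited log2 fold change of 18 h against 2 h equalled the difference of both comparisons with mock to within 1.02e-14. The 3 deposited comparisons therefore came from 1 fit over all 6 libraries, with 1 estimate of the spread per region and fold changes that were not shrunken.

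The tables held 233332 rows for 2 h against mock, 232956 for 18 h against mock and 233150 for 18 h against 2 h. A region named for more than 1 gene had a row for each name, and the 6526, 6522 and 6524 repeat rows were left out, so that each region was counted once. That left 226806, 226434 and 226626 regions, of which 226314 were in all 3 tables. The region end minus the region start was 501 bases for 226860 of the 226920 regions found in any table and 1002 bases for the other 60. Coordinates are given as the files give them, on hg38; whether the files count from 0 or from 1 was not stated, so a start may differ by 1 base.

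The authors wrote an adjusted p of exactly 1 for every region with a mean signal under a limit of 56.2 (2 h against mock), 101 (18 h against mock) or 41.7 (18 h against 2 h). These regions were treated as not tested. Benjamini-Hochberg adjustment of the remaining deposited p-values returned the deposited adjusted p to within 4.99e-14 or less in each table. Among the regions not tested, 118, 45 and 139 had an unadjusted p under 0.001, against 141, 171 and 118 that chance alone gives. The tested regions numbered 86137, 55341 and 108134. A region was called where the authors' adjusted p was under 0.05, and the sign of the deposited log2 fold change gave the direction.

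The test planned for read counts could not be used on these values, so the branch fixed for tables with no values per library applied: the authors' deposited fold changes and adjusted p were counted and compared, and no model was fitted anew. The groups, the comparisons, the threshold, the gene lists and the rule for named genes were fixed before the data were examined. Alternatives that needed values per library were not run (other scalings, other count models, other pseudocounts, fits on 4 libraries, a replicate term, leaving out libraries). Base composition of the regions was not analysed here, since no genome sequence was at hand.

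Named regions followed a fixed rule. For each comparison these were the 12 called regions with the highest and the 12 with the lowest log2 fold change among those with a mean signal at or above the median tested region and a gene name that is not a LOC, LINC or MIR name, 1 region per gene, and then up to 6 per direction within 1 kb of a gene start. Up to 4 called members of each gene list were named, or 2 members with the smallest p where none was called. HMGA1 was always included. A few regions that met the rule are not reported here. The rule's demand that both libraries of one group lie above both of the other could not be applied. A gene name is the one in the deposited table; it says which gene start the region was assigned to, not that the region regulates that gene.

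Of 19059 gene names in the tables, 18348 matched a name in the RefSeq annotation of GRCh38.p14, 936 of them through an older name. That annotation gave the spans of protein-coding genes; exons, introns and untranslated regions were not analysed here. Location was compared with Fisher's exact test (two-sided) in 48 tests with Benjamini-Hochberg adjustment. Its units were regions, which are not independent replicates. The 22 gene lists were melanocyte lineage and pigmentation, undifferentiated or invasive melanoma state, AP-1 and immediate early genes, NF-kB targets, interferon response, antigen presentation, MAPK pathway output, TGF-beta targets, genes linked to HMGA1 in tumours, HMGA1 receptor-related genes, cell cycle, heat shock and protein stress, hypoxia and glycolysis, endocytosis, cholesterol and lipid synthesis, chromatin factors, homeobox and developmental regulators, housekeeping promoters, and markers of keratinocytes, fibroblasts, immune cells and endothelial cells. Each gene was represented by its nearest region within 1 kb of the gene start, and the median log2 fold change of a list was placed among 10000 random lists matched on mean signal. Added after the data were seen, all regions named for a list's genes were counted and set against 10000 random gene sets matched on the number of tested regions per gene, in 132 tests, and 2 further lists (YAP and TEAD targets, SRF and actin genes) were counted in the same way.

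Both comparisons with mock share the mock libraries. The correlation and the overlaps that this alone gives were simulated in 100 draws of unchanged groups with the deposited standard errors. Likewise, regions picked by one comparison and read in another that shares a group were set against 100 draws in which the picked fold change was all noise, a check added after the data were seen. To look at 18 h in regions picked without the noise of that comparison, 2 h was contrasted with the precision-weighted mean of mock and 18 h, whose error is independent of that of 18 h against mock; this contrast was also chosen after the data were seen. Further alternatives were an adjusted p under 0.01, a 2-fold minimum, no limit or a higher limit on mean signal, only regions near gene starts, a 3 kb window, and fold changes centred on the median tested region or within 20 bins of mean signal.

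The depth of each library is unknown. The precision is that of the deposited standard errors, with a median over tested regions of 0.21, 0.16 and 0.24 on the log2 scale, which puts 95% intervals at ± 0.41, ± 0.32 and ± 0.46. The counting and adjustment steps were tested on simulated data with the deposited standard errors. At 2 h against mock, with 86137 regions, 23 of 100 regions changed 1.5-fold and 69 of 100 changed 2-fold were recovered, with 4 false calls among 96. At 18 h against mock, with 55341 regions, 42 and 96 of 100 were recovered, with 5 false calls among 143. At 18 h against 2 h, with 108134 regions, 15 and 54 of 100 were recovered, with 4 false calls among 73. Only these 100 regions per fold were changed in each simulation. The deposited tables had 1100, 67 and 3758 calls, and more calls make the adjusted threshold less strict. The simulated shares therefore understate recovery at 2 h against mock and at 18 h against 2 h, and they do not rank the comparisons. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.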

Results

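Chromatin accessibility was profiled by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in A375 cells, an established human melanoma line. Cells were left untreated (mock) or given recombinant HMGA1 for 2 h or 18 h, with 2 libraries in each of the 3 groups. HMGA1 is an architectural chromatin protein whose AT hooks bind the minor groove of AT-rich DNA, and the series concerns its uptake by melanoma cells. The values are the authors' fold changes over 226920 regions, with 1 mean signal per region over the 6 libraries. The depth of each library is unknown, and the precision is that of the authors' standard errors (SE).

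The comparison of 2 h with mock asked where accessibility changed soon after the protein was added. After 2 h, 737 regions were higher and 363 lower than in mock among the 86137 tested in the authors' deposited table (DESeq2, adjusted p under 0.05). The highest log2 fold change was 1.90 ± 0.21 (SE; adjusted p = 3.50e-14 in the authors' deposited table), at a region on chromosome 15 (39597716 to 39598217) inside the span of THBS1, which encodes the secreted matrix glycoprotein thrombospondin. The called regions moved by a median of 1.69-fold upward and 1.46-fold downward, and 155 of the higher and 9 of the lower regions moved at least 2-fold. They were named for 613 genes (higher) and 335 genes (lower).

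Other regions that rose at 2 h lay at a range of distances from gene starts. In the authors' deposited table, the log2 fold change was 1.28 ± 0.17 (SE; adjusted p = 3.53e-10) at 97.8 kb from the start of CDC42BPA, a kinase that acts on actomyosin (chromosome 1, 227416302 to 227416803). It was 1.24 ± 0.21 (adjusted p = 4.29e-06) for SEMA3A, which encodes a secreted guidance factor, at 442 kb, in the authors' deposited table, and a region 3.46 kb from the epidermal barrier gene FLG rose 2.30-fold (adjusted p = 4.93e-11). For CLPTM1L and THRB, a thyroid hormone receptor gene, the authors' deposited table gave 1.11 ± 0.14 and 1.08 ± 0.19. A region of GAS6, a ligand of the receptor kinase AXL, rose 2.15-fold in the authors' deposited table. The regions of SPATA8, ANKRD10 and TUSC1 (15.3, 52.1 and 587 kb from the gene starts) rose by 1.16 ± 0.19, 1.14 ± 0.18 and 1.07 ± 0.15 there. Within 1 kb of a gene start, the highest named region in the authors' deposited table was that of GJA5, a gap junction gene, at 1.09 ± 0.20 (adjusted p = 5.55e-05). It was followed in the authors' deposited table by DDAH1 (0.84 ± 0.18), FAM186A (0.75 ± 0.17), PDCD1LG2, which encodes an immune checkpoint ligand (0.74 ± 0.15), ANKRD1 (0.72 ± 0.15) and ANXA3 (0.68 ± 0.19).

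Among regions with at least the median mean signal, those that fell at 2 h were led by one of XPNPEP1, an aminopeptidase gene, which fell 2.01-fold (adjusted p = 4.93e-11) at 11.4 kb from its start in the authors' deposited table (chromosome 10, 109935001 to 109935502). TSPYL5, the spectrin gene SPTBN1 and ZSWIM6 followed at -0.95 ± 0.17, -0.93 ± 0.19 and -0.92 ± 0.20 in the authors' deposited table. ABCA8, ZFAND5, ZCCHC24 and the amino acid transporter gene SLC38A1 stood at -0.91 ± 0.14, -0.91 ± 0.15, -0.88 ± 0.15 and -0.86 ± 0.18 there. For TBL1XR1, ARHGAP26, the ephrin receptor gene EPHA7 and the arrestin gene ARRB1 the authors' deposited table gave -0.85 ± 0.17, -0.84 ± 0.19, -0.84 ± 0.17 and -0.83 ± 0.16. These regions lay 418, 21.8, 1188 and 8.98 kb from the gene starts. Within 1 kb of gene starts, a region 803 bases from that of SLC7A5 fell by 0.76 ± 0.13 (adjusted p = 1.41e-05) in the authors' deposited table. The region at the SLC7A5 start itself was not called. KCND1 fell by 0.68 ± 0.19 and FXYD3 by 0.63 ± 0.11 in the authors' deposited table. SHROOM4, NR2F6 and ZNRF1 had -0.50 ± 0.12, -0.45 ± 0.12 and -0.40 ± 0.11 in the authors' deposited table.

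The split between higher and lower calls at 2 h depended on the centring of the fold changes, whose median over the tested regions was -0.06 in the authors' deposited table. The 737 higher calls were 67.0% of all calls as deposited. Centring on the median tested region gave 1179 higher and 198 lower calls (85.6% higher), and centring within bins of mean signal gave 1249 and 173 (87.8%). With the latter, the 2 h calls at NR2F6 and ZNRF1 and, among the list members named below, at SOX9, TXNRD1, NDRG1 and DNM1 were lost.

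Calls clustered at THBS1 and SLC7A5. Of the 15 tested regions that touch the THBS1 span (chromosome 15, 39581079 to 39599466), 13 rose at 2 h, with a median of 1.43, whereas the region at the gene start (39580892 to 39581393) had 0.10 ± 0.09 (SE) and was not called in the authors' deposited table. The median over the 12 of these regions tested at 18 h against mock was 0.08, and 13 of 15 fell from 2 h to 18 h, with a median of -1.27. SLC7A5, on chromosome 16 (87830023 to 87869507), encodes a transporter of large neutral amino acids. Of 18 tested regions touching its span, 7 rose at 2 h (median 1.25) and 1, at 803 bases from the start, was the one that fell. From 2 h to 18 h, 15 of 25 tested SLC7A5 regions fell and 1 rose.

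**Figure D1:**
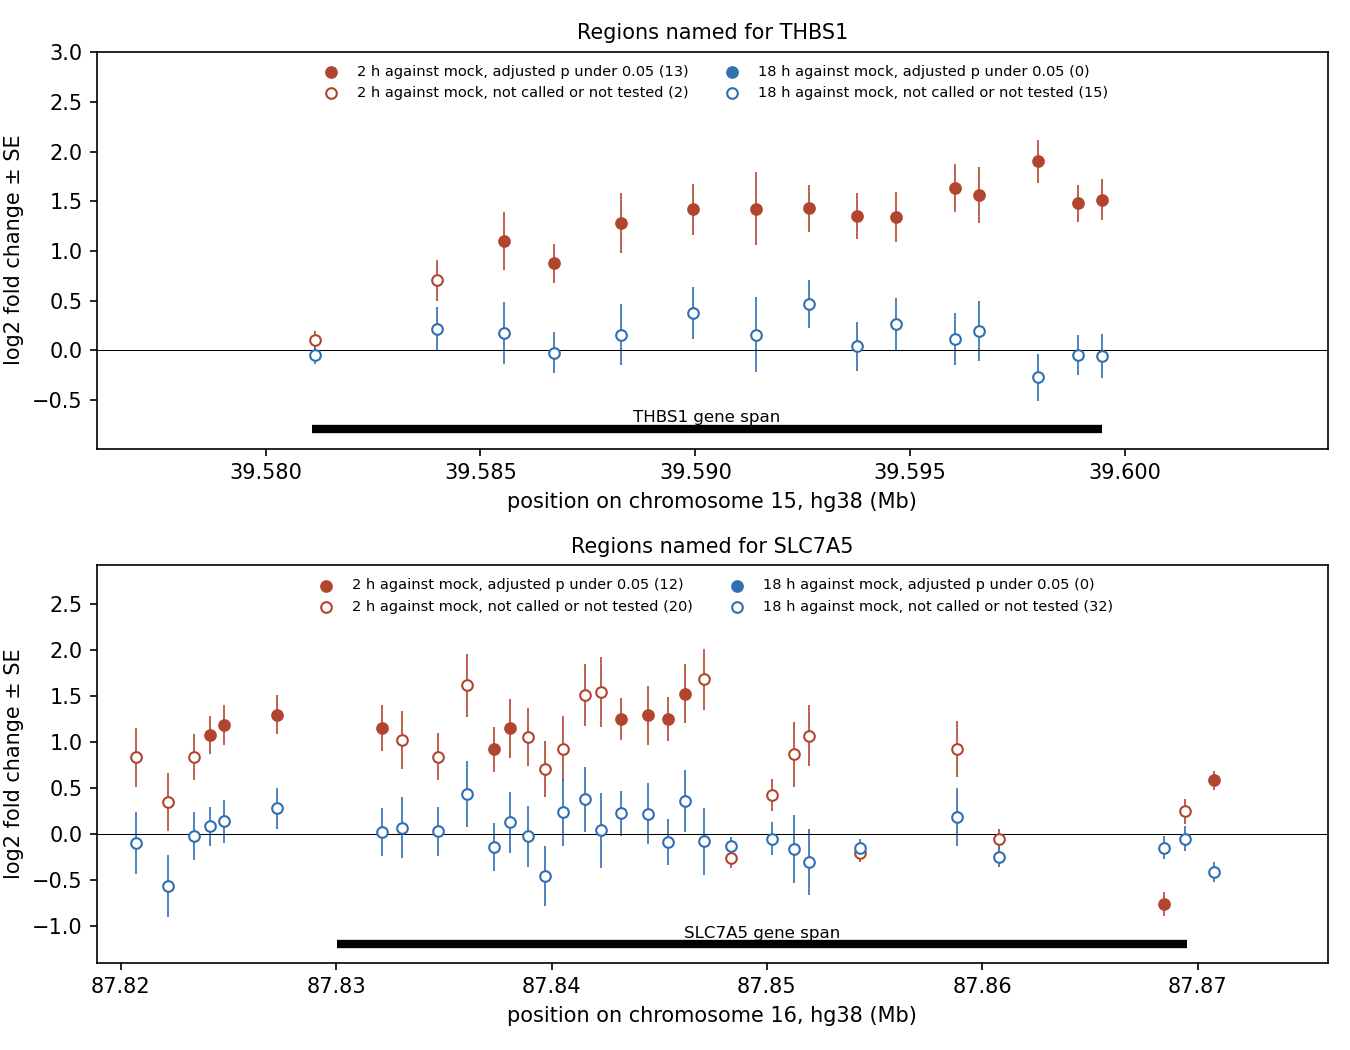
Log2 fold change (± SE, from the authors' deposited table) of regions named for THBS1 (top) and SLC7A5 (bottom) against position in hg38 in Mb, red for 2 h against mock and blue for 18 h against mock, with filled points for adjusted p under 0.05 and the gene span as a black bar. At THBS1, 13 of the 15 plotted regions were called at 2 h and the 18 h values lay near 0.

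The fixed gene lists were first read at gene starts. At 2 h, 0 of 351 list entries with a tested start region were called by DESeq2 in the authors' deposited table, and 45 had an unadjusted p under 0.05. Adjusted over the list alone, 2 of 21 AP-1 and immediate early genes, 3 of 17 genes of MAPK pathway output and 1 of 15 homeobox and developmental regulators were lower. Start regions in general lay below mock in the uncentred values, with a median of -0.11 in the random lists matched to each of these 3 lists, and the MAPK and homeobox lists were not outlying among them (38.5 and 21.1 percentile), so these calls may largely reflect this offset. The AP-1 and immediate early genes had a median log2 fold change of -0.17, which lay at the 0.05 percentile of matched random lists, but averaged over all regions of each gene it was -0.10 (15.1 percentile). JUNB, an AP-1 subunit, had -0.31 ± 0.09 (SE; adjusted p = 0.062) in the authors' deposited table. The undifferentiated or invasive melanoma list had a median of -0.05 over 22 genes, at the 99.8 percentile (0.0088 and 99.1 when averaged over all regions), and its members with the smallest p, CCN2 and CCN1, had 0.32 ± 0.12 (adjusted p = 0.234) and 0.21 ± 0.11 (adjusted p = 0.497) in the authors' deposited table. The medians of the other lists lay within the central 95% of matched random lists. Over all lists, medians ranged from -0.17 to -0.04.

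Away from gene starts, lists held called regions at 2 h, but no list held more than matched random gene sets after adjustment (smallest adjusted p = 0.330 at this comparison). The undifferentiated or invasive melanoma list had 18 of 440 tested regions higher, at 6 genes, 13 of them at THBS1, and 3 lower. Its called members included TNC, a matrix gene, at 0.78 ± 0.19, CD44 at -0.75 ± 0.18 and SOX9 at -0.42 ± 0.10 (SE, authors' deposited table). The regions lay 89.3, 77.3 and 451 kb from these gene starts. The melanocyte lineage list had 3 of 163 regions higher, named for TRPM1 (0.88 ± 0.16), TFAP2A (0.78 ± 0.16) and KIT (0.78 ± 0.17) in the authors' deposited table. These lay 76.9, 916 and 132 kb from the gene starts. AP-1 and immediate early genes had 4 higher and 5 lower of 284. Among them were MYC at 0.59 ± 0.12 (373 kb from the start) and FOSB at -1.47 ± 0.30 (9.26 kb) in the authors' deposited table. Among NF-kB targets 3 of 140 regions were higher, at CSF2 (0.50 ± 0.10), LIF (0.59 ± 0.13) and NFKBIZ (0.83 ± 0.21) in the authors' deposited table. MAPK pathway output had 10 higher and 4 lower of 418, and the authors' deposited table gave SPRED1 and SPRED2, inhibitors of this pathway, -0.47 ± 0.10 and -0.58 ± 0.13. TGF-beta targets had 6 of 380 higher, with TGFB2 at 0.74 ± 0.13 and SMAD6 at 0.99 ± 0.22 in the authors' deposited table. Genes linked to HMGA1 in tumours had 8 higher and 1 lower of 262. CCND1, which encodes a G1 cyclin, had 1.16 ± 0.26 at 6.55 kb from its start in the authors' deposited table.

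Smaller numbers were seen elsewhere. The HMGA1 receptor-related list had 1 of 69 regions higher, named for HMGB2, at 0.97 ± 0.22 (SE; adjusted p = 0.00388) in the authors' deposited table. The cell cycle list had 3 of 86 higher, all at CCND1, the chromatin list 1 of 150 (CREBBP), and the homeobox list 1 of 76 (FOXA2). Heat shock had 1 of 109 lower (TXNRD1), hypoxia and glycolysis 2 of 168 lower (ENO1 and NDRG1), and endocytosis 1 higher (CAV2) and 1 lower (DNM1) of 134. Of the markers of other cell types, endothelial genes had 3 of 91 higher and fibroblast genes 1 of 94 (POSTN). The endothelial ones were named for CDH5, TEK and KDR, at 265, 45.8 and 112 kb from the gene starts. For 6 lists no region was called at 2 h by DESeq2 in the authors' deposited table; of their start regions at an unadjusted p under 0.05 there were 2 of 22 for interferon response, 1 of 19 for antigen presentation, 4 of 15 for cholesterol synthesis, 2 of 20 for housekeeping genes, and 0 of 5 and 0 of 3 for keratinocyte and immune markers.

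Called regions avoided gene starts. Fisher's exact test takes regions as independent, which they are not, so its p-values do not measure the spread between libraries. Within 1 kb of a gene start lay 14.6% of the regions tested at 2 h, but 9 of the 737 higher regions (1.22%; odds ratio 0.0716, adjusted p = 6.69e-37, Fisher's exact test) and 12 of the 363 lower regions (3.31%; odds ratio 0.199, adjusted p = 4.70e-12). More than 100 kb from the named gene start lay 41.0% of the higher and 36.1% of the lower regions, against 27.1% of those tested. At 18 h against 2 h, 35 of 3220 lower regions (1.09%; odds ratio 0.0746, adjusted p = 1.01e-134) and 19 of 538 higher regions (3.53%; odds ratio 0.256, adjusted p = 2.63e-12) lay within 1 kb of a gene start, against 12.5% of those tested.

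**Figure D2:**
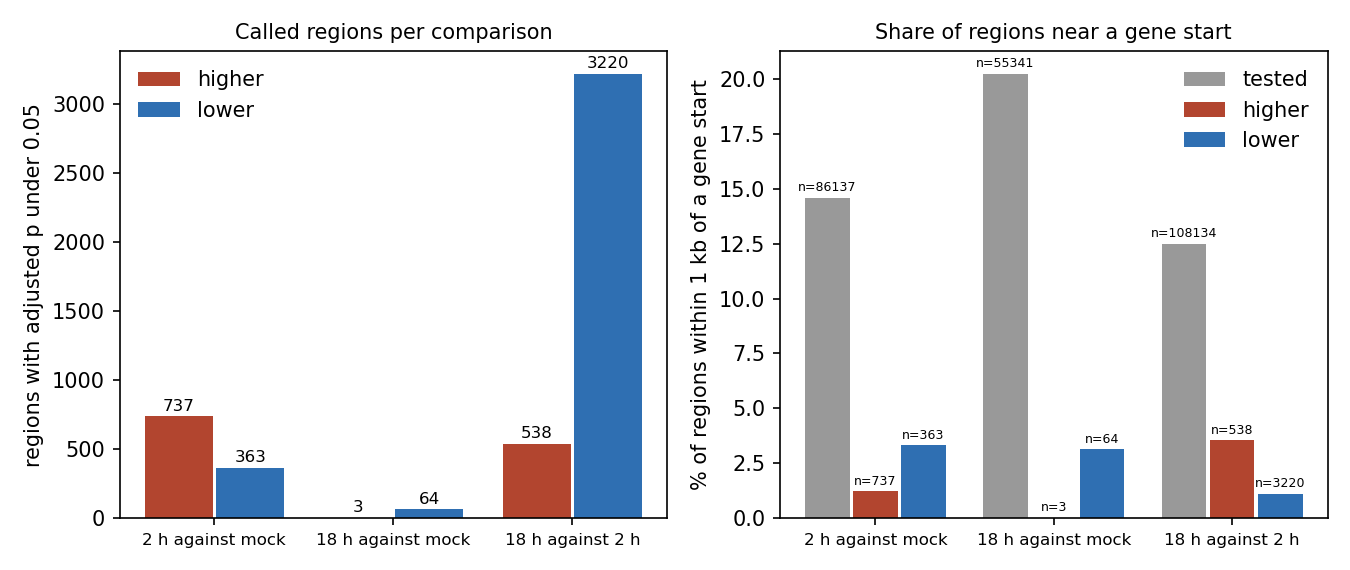
Left, the number of regions with an adjusted p under 0.05 in the authors' deposited tables for each of the 3 comparisons, red higher and blue lower; right, the percentage of tested (grey), higher and lower regions within 1 kb of a gene start, with the number of regions above each bar. Lower regions at 18 h against 2 h (3220) outnumber all other calls, and called regions lie near gene starts less often than tested ones.

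The comparison of 18 h with mock asked which changes were present after the longer exposure. After 18 h, 64 regions were lower and 3 higher than in mock among 55341 tested in the authors' deposited table (DESeq2), and 4367 had an unadjusted p under 0.05. Chance alone gives a share of 0.05 of the tested regions at that p. Their uncentred median of -0.07 adds to those on the lower side. Among regions with at least the median mean signal, the lowest lay 51.3 kb from the start of ABLIM1, an actin-binding gene, inside its span (chromosome 10, 114633195 to 114633696), at -0.78 ± 0.16 (SE; adjusted p = 0.00421) in the authors' deposited table. A region 129 kb from CCND1 (chromosome 11, 69511481 to 69511982) fell by 0.73 ± 0.14 (adjusted p = 0.00353) and one inside SMAD3, a mediator of TGF-beta signalling, by 0.67 ± 0.14 (adjusted p = 0.00549) in the authors' deposited table. The lower regions had a median log2 fold change of -0.56.

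Further regions that fell at 18 h were named for C12orf75 (-0.64 ± 0.14), the tyrosine kinase gene ABL1 (-0.63 ± 0.15), SLC25A48 (-0.63 ± 0.13) and SLC24A2 (-0.63 ± 0.16) in the authors' deposited table. CUEDC1 (-0.62 ± 0.13), RASL12 (-0.61 ± 0.13), LIMD1 (-0.60 ± 0.11), the focal adhesion gene PXN (-0.59 ± 0.14) and HSPG2, which encodes a basement membrane proteoglycan (-0.59 ± 0.14), completed the named set of the authors' deposited table. Near gene starts, 2 of the 64 lay within 1 kb (3.12%, against 20.2% of those tested; odds ratio 0.127, adjusted p = 0.000238, Fisher's exact test): IQCN at -0.54 ± 0.10 and SYNC at -0.42 ± 0.10 in the authors' deposited table. The higher regions were named for TTLL11 (0.64 ± 0.14, adjusted p = 0.0115, in the authors' deposited table), PAX5 (0.83) and REG3A (0.93); PAX5 and REG3A fell outside the naming rule and were picked after their values were seen. As deposited 95.5% of the calls were lower, while centring on the median tested region or within bins of mean signal left 8 lower and 3 higher calls (72.7% lower). Centring within bins of mean signal kept few calls among the 18 h regions that the rule named by fold change, list members aside. Only those of CCND1, LIMD1, IQCN and TTLL11 were kept.

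At gene starts, 0 of 336 list entries were called at 18 h by DESeq2 in the authors' deposited table, 0 when adjusted over the list alone, and 9 had an unadjusted p under 0.05. The AP-1 and immediate early list had a median of -0.14, below every one of the matched random lists, the HMGA1 receptor-related list -0.12 (0.18 percentile, 10 genes), and the keratinocyte list -0.20 (1.81 percentile, 3 genes). Averaged over all regions of each gene, AP-1 stayed below every random list at -0.15, while the receptor-related and keratinocyte lists moved to -0.10 each (5.11 and 9.60 percentile). AP-1 was not alone under this averaging: the undifferentiated or invasive (-0.14), endocytosis (-0.14), MAPK (-0.13), HMGA1-linked (-0.12) and TGF-beta (-0.11) lists all lay below the 1 percentile. In the receptor-related list, SDC4, a cell-surface proteoglycan gene, had -0.29 ± 0.12 (SE; adjusted p = 0.458) and CAV1 -0.13 ± 0.08 (adjusted p = 0.790) in the authors' deposited table. Away from gene starts, called list members besides CCND1 were MYC (-0.43 ± 0.10), FOSB (-1.62 ± 0.39), TGFBI (-0.54 ± 0.10), COL1A1 (-0.59 ± 0.13) and the glucose transporter gene SLC2A1 (-0.51 ± 0.10) in the authors' deposited table. Of these, CCND1 and TGFBI kept their call with centring within bins of mean signal, and MYC, FOSB, COL1A1 and SLC2A1 did not. The MYC, FOSB and CCND1 regions are not the ones given above for 2 h. The MYC region given there, 373 kb from the start, had -0.17 ± 0.13 (adjusted p = 0.854, DESeq2) at 18 h. The MYC region called at 18 h, at 74.6 kb, had 0.32 ± 0.10 (adjusted p = 0.061, DESeq2) at 2 h. No list held more called regions than matched random gene sets after adjustment (smallest adjusted p = 0.333).

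The comparison of 18 h with 2 h tested the difference of both effects directly. From 2 h to 18 h, 3220 regions fell and 538 rose among 108134 tested in the authors' deposited table (DESeq2), by a median of 1.68-fold and 1.55-fold, and 766 and 49 of them moved at least 2-fold. The THBS1 region that led at 2 h fell by 2.18 ± 0.22 (SE; adjusted p = 1.33e-18) in the authors' deposited table. Regions of UBE2E2, a ubiquitin-conjugating enzyme gene, and SMAD6, an inhibitor of BMP and TGF-beta signalling, had -1.68 ± 0.24 (adjusted p = 2.24e-09) and -1.67 ± 0.23 (adjusted p = 3.35e-10) in the authors' deposited table. IRS2, which encodes an insulin receptor substrate, had -1.49 ± 0.20 (adjusted p = 8.28e-11) at 512 kb from its start in the authors' deposited table (chromosome 13, 109274090 to 109274591).

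In the same direction, the authors' deposited table gave GSDMC -1.59 ± 0.24, FRMD4A -1.51 ± 0.22, TSEN15 -1.48 ± 0.16, LMO7DN -1.48 ± 0.24, LRTM1 -1.48 ± 0.19, FAT3 -1.48 ± 0.22 and MYO9B -1.45 ± 0.18. Near gene starts, GJA5 (-1.27 ± 0.20), KRTAP4-9 (-1.17 ± 0.24), ANXA3 (-1.16 ± 0.19), DDAH1 (-1.07 ± 0.18), FAM186A (-1.01 ± 0.17) and EHBP1 (-0.92 ± 0.21) fell in the authors' deposited table. Regions with at least the median mean signal that rose were led by CCDC192 at 1.22 ± 0.23 (adjusted p = 2.34e-05), EPHA7 at 1.15 ± 0.17 (adjusted p = 1.40e-08) and SPTBN1 at 1.09 ± 0.19 (adjusted p = 2.48e-06) in the authors' deposited table. DENND6A and SLC34A2 had 1.04 ± 0.20 and 1.03 ± 0.24, and regions of ALDH8A1 and the nuclear receptor cofactor gene NRIP1 rose 2.01-fold and 2-fold, in the authors' deposited table. LPIN1, the hyaluronan synthase gene HAS2, FYB1, RAPGEF2 and RP11-566D24.2 had 0.99 ± 0.16, 0.99 ± 0.21, 0.98 ± 0.24, 0.97 ± 0.19 and 0.97 ± 0.18 there. Within 1 kb of gene starts KCND1 (0.72 ± 0.18), SLC7A5 (0.61 ± 0.13), HOXA5 (0.58 ± 0.16), SHROOM4 (0.55 ± 0.12), the retinoic acid receptor gene RARB (0.54 ± 0.17) and FXYD3 (0.52 ± 0.11) rose in the authors' deposited table. RARB lost its call with centring within bins of mean signal. The SLC7A5 region is the one 803 bases from the start, and the region at the start itself was not called.

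Of 361 list entries with a tested start region, 2 were called at 18 h against 2 h, both higher, and 21 had an unadjusted p under 0.05. They were CD74, which encodes the invariant chain of antigen presentation (0.30 ± 0.08 SE, adjusted p = 0.00702), and HOXA5 (adjusted p = 0.0135), in the authors' deposited table; adjusted over the list alone, the same counts of 1 antigen presentation and 1 homeobox gene held, and 1 gene of the undifferentiated or invasive list was lower. The undifferentiated or invasive list had a median of -0.02 (0.19 percentile), and the heat shock and fibroblast lists 0.10 and 0.22 (98.0 and 98.1 percentile, the latter over 5 genes). Start regions in general lay above 0 here, with medians of 0.06, 0.06 and 0.04 in the random lists matched to these 3. Averaged over all regions of each gene, the undifferentiated or invasive list had -0.13, below every random list, and AP-1, NF-kB and MAPK lists also lay low at -0.07, -0.07 and -0.06 (0.3, 0.44 and 2.4 percentile). Housekeeping genes lay high at 0.09 (98.3 percentile), while heat shock moved to 0.03 (48.9 percentile) and the fibroblast list to -0.06 (9.04 percentile). Counting every region named for a list's genes, the undifferentiated or invasive list had 53 of 552 regions lower (9.60%, against a median of 3.86% in matched random gene sets), at 12 genes, with an unadjusted p of 0.0014 and an adjusted p of 0.185. THBS1 alone held 20 of these regions. AXL, a receptor kinase gene, NUAK1 and EGFR were also among the genes, at -0.84 ± 0.13, -1.48 ± 0.25 and -0.67 ± 0.12 in the authors' deposited table. Genes linked to HMGA1 in tumours had 28 of 318 regions lower (8.81%, against 3.19%; unadjusted p = 0.0081 by permutation), the cell cycle list 10 of 110 (9.09%, against 1.98%; p = 0.0055, all at CCND1) and TGF-beta targets 32 of 459 (6.97%, against 3.62%; p = 0.0278). CCND1 and MYC held 10 and 8 of the lower HMGA1-linked regions, and TGFB2 held 9 of those of TGF-beta targets. MAPK pathway output had 34 of 525 lower (6.48%, against 4.03%) and AP-1 and immediate early genes 17 of 348 (4.89%, against 3.31%). The same CCND1 and MYC regions count in the MAPK list, and those of MYC in the AP-1 list. Interferon response had 3 of 89 lower (OAS2, MX1 and OASL), keratinocyte markers 3 of 58, immune markers 1 of 44, cholesterol synthesis 2 of 118 and housekeeping genes 3 of 116 lower and 1 higher. No list passed adjustment.

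The changes of 2 h were set against the later values in the same regions. Regions picked for a 2 h change and read at 18 h against 2 h share the 2 h libraries, so noise alone favours a return. The value that unchanged groups give was simulated with each picked fold change taken as all noise. This used the deposited standard errors, with 1 spread per region for all groups. If the 2 h libraries were noisier than the mock libraries, unchanged groups would return more often, so noise is not excluded. Of the 737 regions that rose at 2 h, 679 (92.1%) fell from 2 h to 18 h, against 80.2 without change (10.9%), with medians of 0.76 at 2 h and -0.13 at 18 h against mock in the authors' deposited tables (0.40 at 18 h without change). Of the 363 regions that fell at 2 h, 140 (38.6%) rose from 2 h to 18 h, against 51.7 without change (14.2%), with medians of -0.55 and -0.15 (-0.25 at 18 h without change). The 3220 regions lower at 18 h than at 2 h had medians of 0.45 at 2 h and -0.28 at 18 h against mock in the authors' deposited tables; noise alone gave 0.33 and -0.39, so these medians carry little information on their own. Of the 3220, 679 were called higher at 2 h and 36 were called lower at 18 h. The 538 regions higher at 18 h than at 2 h had medians of -0.45 and 0.16, against -0.33 and 0.27 from noise alone, and 140 were called lower at 2 h.

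**Figure D3:**
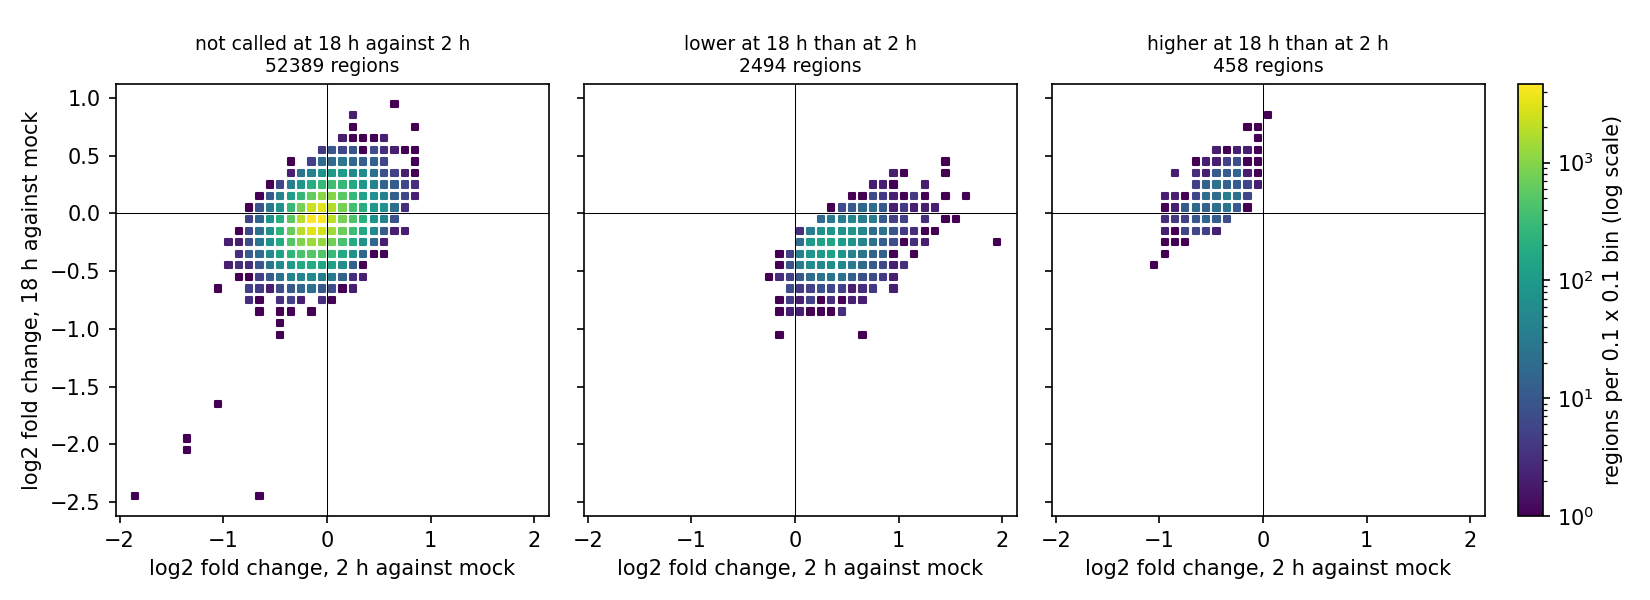
Log2 fold change of 18 h against mock (vertical) plotted against that of 2 h against mock (horizontal) for the 55341 regions tested in both, in squares coloured by the number of regions on a log scale, split by the call at 18 h against 2 h in the authors' deposited tables. Regions lower at 18 h than at 2 h lie mostly above mock at 2 h and below mock at 18 h, a layout that noise alone also gives in regions picked this way. Of all plotted regions, 69.5% lie below mock at 18 h.

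Both comparisons with mock share the mock libraries, which alone ties their values together. Across the 55341 regions tested in both, which are not independent replicates, Pearson's r of the fold changes in the authors' deposited tables was 0.0992 and Spearman's coefficient 0.137, while unchanged groups simulated against the same mock libraries gave r of 0.498. The covariance was 0.00347 against 0.0144 (SD 0.00016) in the simulation, a difference of -0.011, and 62.5% of the regions had the same sign against 66.6%. Called lower at both times were 7 regions, among them those of C12orf75, CUEDC1 and LIMD1, while lists of the same length from unchanged groups that share the mock libraries had 11 in common on average (5 to 19 over the draws), so the 7 are no excess. Higher at both times was 1 region (1.18 without change), higher at 2 h and lower at 18 h were 3 (0 without change), and lower then higher 0 (0 without change; DESeq2). At an unadjusted p under 0.05 in both, 653 regions were lower at both times (255 without change), 44 higher at both (254), 416 higher then lower (0.22) and 18 lower then higher (0.20). The fold changes were not centred here, and the mock libraries could not be split because no column holds the values of 1 library. The simulations took 1 spread per region for all groups. With less noisy mock libraries they would give a lower correlation and fewer regions called in the same direction at both times.

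HMGA1 itself has its own gene start among the regions. The region at the start of HMGA1 (chromosome 6, 34236660 to 34237161) had log2 fold changes of -0.26 ± 0.18 (SE; adjusted p = 0.704) at 2 h and 0.01 ± 0.17 (adjusted p = 0.999) at 18 h against mock, and 0.27 ± 0.18 (adjusted p = 0.657) at 18 h against 2 h, in the authors' deposited tables. None of the 3 passed the test.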

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

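The tests of signal over background, of a single 2 h library and of noisier 18 h libraries, the contrast that selects regions without the noise of 18 h against mock, and the simulation of unchanged groups in picked regions, were chosen only after the result was seen.

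The effects at 2 h and 18 h differed by the direct test of 18 h against 2 h, with 3220 regions lower and 538 higher. The same test separated both times at 29 of the regions named as highest or lowest in the comparisons with mock. Those were 12 per direction at 2 h, and 12 lower and 1 higher at 18 h. Further regions named near gene starts or as list members also passed and were not counted. The counted regions were picked on libraries that the test uses again, which favours a difference. With the picked fold changes taken as all noise, 4.77 of the 12 highest and 5.37 of the 12 lowest regions at 2 h were called on average, against 12 and 10 observed. Of the 12 lowest at 18 h against mock it was 2.89, against 7, which the highest draw also reached. These draws too took 1 spread per region for all groups. Among regions that rose at 2 h, the log2 fold change of 18 h against 2 h in the authors' deposited table was -2.18 at THBS1, -1.30 at CDC42BPA, -1.32 at SEMA3A, -1.45 at FLG, -1.02 at SPATA8, -1.25 at ANKRD10, -1.34 at CLPTM1L, -1.30 at GAS6, -1.31 at KALRN, -1.27 at GJA5, -1.35 at THRB and -1.16 at TUSC1. Among regions that fell at 2 h it was 0.58 at XPNPEP1, 0.73 at TSPYL5, 1.09 at SPTBN1, 0.74 at ZSWIM6, 0.90 at ABCA8, 0.52 at ZFAND5, 0.61 at SLC38A1, 0.72 at TBL1XR1, 0.89 at ARHGAP26 and 1.15 at EPHA7 in the authors' deposited table. Among regions that fell at 18 h against mock it was -0.95 at ABLIM1, -0.66 at CCND1, -0.63 at ABL1, -0.96 at SLC25A48, -0.95 at RASL12, -0.75 at PXN and -1.01 at HSPG2 in the authors' deposited table.

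The first pattern is the excess of lower over higher regions at 18 h against 2 h. Scaling of the libraries was argued against, because 87.6% of the calls were still lower after centring within bins of mean signal. A difference in signal over background between the 2 h and 18 h libraries would move all regions of the same mean signal and distance class; their median was -0.0037 on the log2 scale. One aberrant 2 h library cannot be told apart from an effect of the treatment, since 0 columns hold the values of 1 library. A biological difference between 2 h and 18 h of exposure stays open as untested, as does any change with time in culture, because the labels do not say when the mock cells were taken.

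The second pattern is a level below mock at 18 h in regions that stood apart upward at 2 h. In 2240 such regions, picked by a contrast whose error is independent of 18 h against mock, the median of 18 h against mock was -0.21, and -0.14 relative to regions of the same mean signal (95% interval over resampled chromosomes -0.15 to -0.13, negative on 23 of 23 chromosomes). All chromosomes were read from the same 6 libraries, so this interval leaves out the spread between libraries. The lower 18 h level in regions picked this way argues against noise of the shared mock libraries as the cause. 18 h libraries noisier than the mock libraries could give part or all of it and cannot be told apart here: the covariance of both contrasts was -0.0102, between 0 and the -0.0138 that unequal noise alone allows. Among the 914 regions that stood apart downward at 2 h, the same median was 0.06 relative to regions of the same mean signal (0.05 to 0.08).

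The third pattern is the scarcity of called regions near gene starts. Lower precision near gene starts was argued against, since the median standard error there was 0.533 times that of other tested regions at 18 h against 2 h. Other mean levels near gene starts were argued against as well, because 54 regions were called there against 958 expected from other regions of the same mean signal, a ratio of 0.0564. The design names no group that bears on this pattern, and no biological explanation was tested.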

How the results depend on the processing

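Centring, the use of the regions tested in all comparisons and the counting of repeat rows were chosen only after the result was seen. No paired analysis was possible because no column holds the values of 1 library; for the same reason other scalings, other count models, pseudocounts, fits on 4 libraries, a replicate term and leaving out libraries were not run, and base composition was not analysed here because no genome sequence was at hand. At an adjusted p under 0.01, calls numbered 377 higher and 129 lower at 2 h, 1 and 23 at 18 h against mock, and 224 and 1896 at 18 h against 2 h, and regions lower at both times 3 in place of 7; the odds ratio of lying near a gene start for regions lower at 18 h was then 0.179 with an adjusted p of 0.119, over 23 regions. With a 2-fold minimum, calls were 155 and 9, 0 and 4, and 49 and 766. With p adjusted anew over regions within 1 kb of a gene start alone, they were 5 and 4, 0 and 1, and 4 and 19. The calls as deposited numbered 9 and 12, 0 and 2, and 19 and 35 there. The stricter threshold and the 2-fold minimum keep fewer regions by construction. The 0 higher calls at 18 h stand beside 4367 regions of either direction at an unadjusted p under 0.05 (DESeq2). Chance alone gives a share of 0.05 of the 55341 tested at that p. With no limit on mean signal, lower calls fell to 206 at 2 h, 205 of them also called as deposited, and to 32 at 18 h against mock, 29 of them also called as deposited. With mean signal at or above the median tested region, 18 h against mock had 1 higher and 102 lower calls. Centring on the median tested region gave 1179 higher and 198 lower calls at 2 h and 8 lower at 18 h against mock, and centring within bins of mean signal 1249, 173 and 8; the 737 higher calls were all among the centred ones. The median of 18 h against mock in regions upward at 2 h went from -0.21 to -0.14 relative to regions of the same mean signal. Averaging over all regions of a gene turned the sign of 3 list medians: to 0.0088 for the undifferentiated or invasive list and 0.090 for YAP and TEAD targets at 2 h against mock, and to -0.057 for fibroblast markers at 18 h against 2 h; another 44 list medians moved, among them that of AP-1 and immediate early genes at 2 h, and 25 did not; the cause was not tested. Of the named regions, 299 kept their side of the threshold with centring within bins of mean signal, 24 lost it and 3 gained it; with no limit on mean signal 300 kept it and 26 lost it. A 3 kb window moved 2 of 72 list medians, and raised the odds ratio of lying near a gene start from 0.0746 to 0.182 for regions lower at 18 h against 2 h and from 0.127 to 0.204 for those lower at 18 h against mock, both still under 1 with adjusted p of 6.77e-129 and 0.000355. All other counts of called regions stayed within 1.5-fold of those reported. The depth per library is unknown. At the deposited precision, 15 of 100 simulated 1.5-fold changes were recovered at 18 h against 2 h. That simulation had 73 calls against 3758 in the data, so its adjusted threshold was stricter and this share understates recovery.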

Other observations

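The tests of YAP and TEAD targets, of SRF and actin genes and of precision at 18 h, and the count of genes with many called regions, were chosen only after the result was seen.

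The 3220 regions lower at 18 h than at 2 h were spread over 2155 genes, but some genes held more than random placement gives. Of 17336 named genes, 36 had at least 5 regions lower at 18 h than at 2 h. The mean was 3.47 and the highest value 10 when the calls were placed at random 1000 times (permutation test, p = 0.001, the smallest these draws can give). The placement took regions as independent, although neighbouring ones moved together, so this p-value does not measure the spread between libraries. THBS1 and SLC7A5 had 20 each, IRS2 15 of 64 tested regions and PLEC, which encodes the cytoskeletal linker plectin, 15 of 23. Of the 23 tested regions touching the PLEC span (chromosome 8, 143915153 to 143976745), 15 fell from 2 h to 18 h, with a median of -1.18 in the authors' deposited table, and their median against mock was 0.63 over 18 tested at 2 h, 1 of them called, and -0.07 over 5 tested at 18 h. CCND1 and CRIM1 had 10 each.

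Some regions of immediate early genes fell, and some that were called lower at 1 time also lay below mock at the other. A region 9.26 kb from the start of FOSB had -1.47 ± 0.30 (SE; adjusted p = 0.000622) at 2 h, and one 3.79 kb from it, inside the gene span, had -1.06 ± 0.39 (adjusted p = 0.185) at 2 h and -1.62 ± 0.39 (adjusted p = 0.0356) at 18 h, in the authors' deposited tables. MCL1 had -0.98 ± 0.28 (adjusted p = 0.0369) at 2 h in the authors' deposited table. At 18 h against mock the FOSB region at 9.26 kb had -1.75 ± 0.31 and MCL1 -1.25 ± 0.28, both not tested for low mean signal. From 2 h to 18 h neither was called (adjusted p = 0.910 and 0.899, DESeq2). Both comparisons with mock share the mock libraries, whose noise alone carries part of a fall over to the other time. These values thus do not show that the falls lasted. A JUN region had -1.67 ± 0.40 (adjusted p = 0.00249) at 18 h against 2 h, in the authors' deposited table.

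A candidate explanation for the fall between 2 h and 18 h is a YAP or TEAD programme that was open at 2 h, a hypothesis raised by the THBS1 and AMOTL2 regions. Of 451 tested regions named for 22 published targets, recalled from the literature, 66 (14.6%) were lower at 18 h than at 2 h, at 20 genes, against a median of 3.81% in matched random gene sets (permutation test, p = 0.0001, the smallest these draws can give). Without AMOTL2, CRIM1, TGFB2 and AXL, which had the most calls among those seen beforehand, 36 of 310 regions (11.6%) were lower, against 3.70% (permutation test, p = 0.0013). Without every list gene that had been named for another reason, ANKRD1 included, it was 30 of 273, against a share of 3.77% (permutation test, p = 0.0046). At 2 h against mock, 22 of 371 were higher (5.93%, against 1.02%). Averaged over all regions of each gene, the list median was 0.09 at 2 h and -0.17 at 18 h against mock, both uncentred. These lay at the 100 and 0 percentile of matched random lists. Neither extreme was particular to this list. With the same averaging, the undifferentiated or invasive list lay at the 99.1 percentile at 2 h. At 18 h against mock the AP-1 list lay at 0, the endocytosis list at 0.02, and the undifferentiated or invasive and SRF lists at 0.03 each. At 18 h against mock, however, 0 of 231 regions of the list were called by DESeq2, and the matched random sets also had a median of 0%. Of the start regions, 1 of 21 had an unadjusted p under 0.05 (DESeq2). Their median was -0.08 (12.8 percentile, random median -0.05). A level below mock at 18 h thus showed in the average over all regions but not at gene starts. How much of the fall it made up was left open. The log2 fold changes of 18 h against 2 h in the authors' deposited table were -1.19 at TGFB2, -0.94 at AMOTL2 and -0.68 at NUAK2. The random sets were matched on the number of regions per gene and not on expression or distance, and the hypothesis was found and tested on the same data.

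A programme of SRF and actin genes was tested in the same way, after TPM1 had been seen. Of 166 regions, 12 (7.23%, against 3.21%) were lower at 18 h than at 2 h (permutation test, p = 0.03), but without TPM1 it was 6 of 146 (4.11%, against 3.03%; p = 0.268). The result thus rested on TPM1, and this test does not decide the hypothesis.

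Few calls at 18 h against mock could come from lower precision at 18 h, and this stays open. The standard errors of 18 h against mock were 0.992 times those of 2 h against mock in the median, but the fit had 1 estimate of the spread per region for all groups, so a ratio near 1 does not show how precise the 18 h libraries were.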
